A study of Mus musculus with 6 samples.

How the data were processed

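RNA was sequenced from mouse satellite cells, the stem cells of skeletal muscle, kept in growth medium with serum and basic FGF, in 6 libraries at day 4. The labels put 3 libraries in a control group and 3 in an Islr knockout group. The series design states that the cells were sorted by flow cytometry on the presence or absence of Islr. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which can be partly technical.

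The main table deposited by the authors holds 1 value per gene and library on a signal scale: gene counts divided by 1 size factor per library. The submitters' processing notes name Trimmomatic, HISAT2 2.0.5, HTSeq, DESeq2 1.16.1 and edgeR 3.18.1, with no role or order. Strand handling and the annotation used for counting are not given in the sources used here. Of 27093 Ensembl genes in the table, 27065 were found in the GENCODE mouse annotation of GRCm38, and 26940 of these had the same chromosome, start and end, so coordinates are given on GRCm38. Another 273 features were unannotated loci, which were tested and are not named. The table was damaged at 36 lines, which hold the overflow of long annotation cells and were dropped; 27366 features remained, and 25 gene symbols had been turned into dates.

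The library labelled control 1 is tied to its column by a 4-digit name in which 2 digits are exchanged against the label; the other 5 columns equal their labels. The same table holds the log2 fold change, p-value and adjusted p-value of the authors' own comparison, per the file headers. A deposited raw count table covers 1031 features; 480 of these are in the main table, and the other 551 had 0 reads in all libraries. A further deposited table lists GO terms with the number of annotated, listed and expected genes and a p-value for each term, per the file headers; the tool behind it is not given in the sources used here. Another 12 columns of per-sample values were not used.

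The size of 1 read in each library was recovered from the lowest values of its column. All values (100.0%) then came out as whole reads within 0.01, and all 480 genes held in both tables had the deposited raw count. Library totals ran from 16456917 to 20531276 reads and size factors from 0.8581 to 1.1948. Over 14280 genes with a mean of at least 10, the Pearson correlation of libraries ranged from 0.878 to 0.949 within a group, and was 0.98, 0.966 and 0.947 between the control and knockout libraries of numbers 1, 2 and 3. In the most alike pair, of number 1, 6.2% of genes still differed by at least 2-fold. Genes are not independent replicates, and this is a description of the libraries.

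The tests planned before the data were examined were edgeR for counts, or limma for normalized values. As the main table holds scaled values, the limma test was used: limma 3.58.1 (trend and robust options) on log2(scaled reads + 1), over 20344 genes with a mean of at least 1, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. An edgeR 4.0.16 quasi-likelihood test on the recovered reads (14214 genes) was added after the data were seen; its forms with DESeq2 size factors and without robust dispersion had been planned. Alternatives also covered DESeq2 1.42.0, limma-voom, TMM, upper-quartile and library-size scaling, pseudocounts of 0.1 and 0.5, other filters, a replicate block, leaving out each library and leaving out both libraries of 1 replicate number.

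Replicate numbers 1 to 3 occur in both groups. Deviations of same-numbered libraries from their group means correlated at 0.689, 0.633 and 0.625 over 14280 genes, while those of differently numbered libraries correlated between -0.513 and -0.245. As each group is centred on its own mean, these negative values follow in part from the positive ones and are no separate evidence. The numbers were therefore treated as pairing the libraries in the alternatives with a replicate block. The main limma test and the main list test had been planned without a block and ignore this pairing. So do all fits that left out 1 library. There the same-numbered partner stays in unmatched, and differences between replicate numbers enter the comparison of the groups. This pairing comes from the data, since the labels give the numbers without saying what they mark.

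Gene lists were fixed before the data were examined (34 lists, of which 31 had at least 5 tested members). They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists, and with an estimated correlation and with fry as alternatives. Fry asks whether the genes of a list move, on balance, one way and does not compare them with other genes. Genes were named by a rule also fixed then. It takes Islr, Sparc, Pax7, Myf5, Myod1, Myog and Mapk3 always, and 1 further gene that is not reported here. It adds the 8 largest changes per direction among genes past the threshold with a mean of at least 5 and groups that do not overlap, and the 8 genes with the smallest p. For each list it takes up to 4 members past the threshold or, where none passed, the member with the smallest p, given as values. Predicted genes, clone names and pseudogenes were left out, and no gene passed the threshold. Where a symbol stood more than once, the feature with the higher mean was taken. Any other gene is named with the remark that it was chosen after its values were seen.

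The procedures were tested on simulated data with the real means and library sizes, the spread seen between libraries of 1 group and 50 changed genes per fold size. The changed genes, and the members of the raised list, were drawn from genes with a mean of at least 50 scaled reads. Recovery was therefore not measured for lower genes. In the limma test on 20344 genes, 0% of the 2-fold, 46% of the 4-fold, 88% of the 8-fold and 90% of the 16-fold changes were recovered, with 16 false calls. With the smaller spread left after the replicate block, the blocked limma test recovered 46%, 96%, 98% and 100%, with 27 false calls. DESeq2 made more false calls than limma, 70 with the spread between libraries and 34 with the block. It recovered 70% and 96% of the 4-fold changes. A raised simulated list was called by camera, and 0 of 30 unchanged lists were. The simulated genes vary independently, which real lists do not. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1. Scripts ran in R 4.3.3 and Python 3.11.15.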

Results

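Gene expression was measured by RNA sequencing in satellite cells from mouse skeletal muscle at day 4 of growth culture, in 3 libraries labelled control and 3 labelled Islr knockout. Islr encodes a secreted protein with leucine-rich repeats and an immunoglobulin domain. The series title names asymmetric division of satellite cells, Sparc and phosphorylated ERK as the subject. The control libraries held 16835581, 16776805 and 20531276 reads on genes and the knockout libraries 16456917, 19874140 and 20124943 (numbers 1 to 3 in each). Values below are reads scaled by the size factors in the deposited table, with the SD over 3 libraries.

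Islr did not separate the groups library by library. Its level was 181.1, 12.8 and 1579 scaled reads in the libraries labelled control 1, 2 and 3, and 256.7, 7.4 and 10.9 in those labelled Islr knockout 1, 2 and 3. The library labelled Islr knockout 1 thus held more Islr than those labelled control 1 and control 2, against its label. The group means were 591 ± 860 (SD, n = 3) for control and 91.7 ± 143 (SD, n = 3) for knockout, with a log2 fold change of -2.43 ± 2.15 (SE) and a 95% confidence interval from -7.77 to 2.92 (limma adjusted p = 1.0). Islr (ENSMUSG00000037206) lies on chromosome 9 from 58156268 to 58204306 on GRCm38. The annotated span reaches the neighbouring Islr2, so some reads cannot be assigned with certainty; Islr2 stood at 43.3, 2.3 and 32.4 in the control libraries and 62.7, 1.8 and 2.5 in the knockout libraries. The deleted part of Islr is not given in the sources used here, and whole-gene reads from outside it check nothing. Because of this disagreement, groups are named below by the labels of the libraries.

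**Figure D1:**
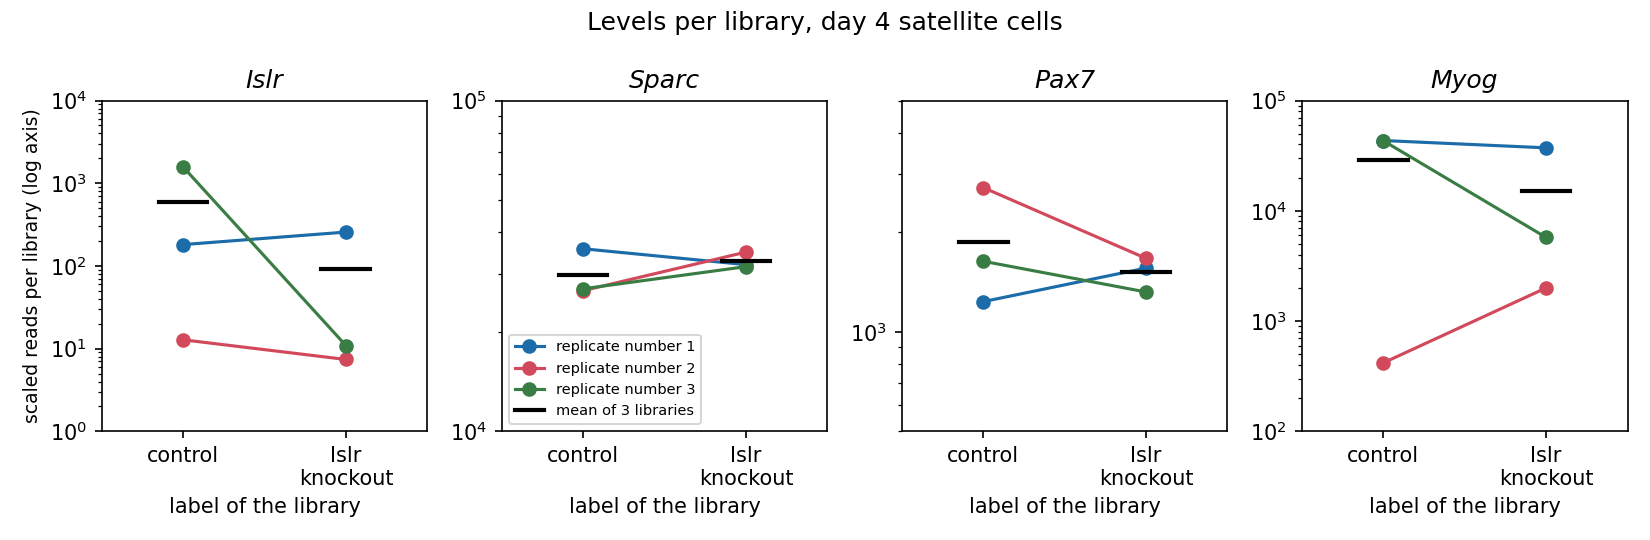
Scaled reads (log axis) of Islr, Sparc, Pax7 and Myog in the 6 libraries, by label; points joined by a line share a replicate number and black bars are the mean of 3 libraries. Islr ran from 7.4 to 1579, and the library labelled Islr knockout 1 (256.7) stood above that labelled control 1 (181.1).

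The next comparison asked which genes differed between the libraries labelled Islr knockout and control. The genes with the smallest p were all higher in each of the 3 libraries labelled knockout than in any labelled control. Fn1, which encodes the matrix glycoprotein fibronectin, averaged 51221 ± 12670 against 22020 ± 4173 scaled reads, a log2 fold change of 1.21 ± 0.30 (SE). Timp3, an inhibitor of matrix metalloproteinases, averaged 478 ± 144 against 220 ± 9.08. Arap2, a GTPase-activating protein, averaged 183 ± 69.1 against 64.9 ± 2.13, and the protocadherin gene Pcdh19 averaged 590 ± 70.0 against 310 ± 61.9. Adgra2, an adhesion G protein-coupled receptor, averaged 479 ± 24.6 against 265 ± 13.3. Fndc3b averaged 2664 ± 640 against 1425 ± 182, and the prostaglandin transporter gene Slco2a1 averaged 414 ± 134 against 166 ± 70.7. Pkd1l1 was near the detection limit, at 4.6, 3.7 and 5.0 scaled reads in the libraries labelled knockout and 0 in the 3 labelled control. None of these differences passed the adjusted threshold (limma adjusted p = 1.0 for each of these 8 genes). Over the alternatives, adjusted p ran from 0.0374 to 1.0 for Slco2a1 and from 0.0614 to 1.0 for Fn1, and the lowest for each of the other 6 was above these.

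Across all 20344 genes tested, 0 passed in limma, and 276 (1.36%) had an unadjusted p under 0.05. Of these, 233 were higher and 43 lower in the libraries labelled knockout. Independent libraries with no difference would give a share of about 0.05. The unblocked test keeps differences between replicate numbers in its error, so its p-values run high and its intervals wide. With the replicate block the share was 4.59%. With other tools the count past the threshold was also 0, with 162 genes at an unadjusted p under 0.05 in edgeR, 131 in limma-voom and 318 in DESeq2. With the replicate number as a block, limma called 0 genes and 933 had an unadjusted p under 0.05, edgeR called 0 with 609, and DESeq2 called 7 with 714. The groups did not overlap in 539 genes higher and 429 genes lower in the libraries labelled knockout, together 4.76% of those tested. Chance gives 10% for exchangeable libraries, and the other 3 splits that part all 3 replicate numbers gave 2.3%, 4.43% and 7.02%. Each of these 3 splits exchanges the labels of 1 replicate number and keeps the other pairs as labelled. A difference between the labelled groups can therefore show in them too, here and below. Leaving out 1 library, without a block and with its same-numbered partner unmatched, moved the limma count of 276 by over 1.5 times. It was 831 without the library labelled Islr knockout 1, 520 without that labelled control 2, and 91 without that labelled Islr knockout 3.

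Sparc, Mapk3 and the myogenic factors did not pass the test. Sparc, a secreted matrix protein, averaged 32734 ± 1822 scaled reads in the libraries labelled knockout and 29744 ± 5111 in those labelled control, a log2 fold change of 0.15 with a 95% confidence interval from -0.44 to 0.74. Mapk3, which encodes a kinase of the ERK pathway, averaged 2438 ± 644 against 2474 ± 418 (interval -0.69 to 0.60), and its log2 fold change came to 0.00 by library size alone and turned positive without the library labelled control 3 (0.07) or Islr knockout 1 (0.18). RNA levels say nothing of ERK phosphorylation. Pax7, the transcription factor of satellite cells, averaged 1515 ± 178 against 1865 ± 774 (interval -0.95 to 0.50; log2 fold change 0.09 without the library labelled control 2), and Myf5, which marks committed cells, 1614 ± 417 against 1894 ± 320 (interval -0.88 to 0.38). The myogenic factor Myod1 was lower in the library labelled knockout in each of the 3 pairs, at 21458 ± 2863 against 30059 ± 5123. Its interval, which ignores the pairs, ran from -1.09 to 0.13. With the replicate block its SE was 0.19 in place of 0.27 (limma unadjusted p = 0.0356, adjusted p = 0.9204). Myog, which marks differentiation, ran from 417.2 to 43370 among the control libraries and from 1998 to 37228 among the knockout libraries. Its log2 fold change was -0.29 ± 2.27 (SE, or 1.09 with the replicate block). This fold change turned positive without the library labelled control 1 (0.82), control 3 (0.82) or Islr knockout 2 (0.66). Without the block, the limma adjusted p was 1.0 for each gene in this paragraph.

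Among gene lists fixed beforehand, those for extracellular matrix, matrix proteases, ERK-responsive, TGF-beta, immediate-early and cytokine genes, and for fibroblast, endothelial, macrophage and Schwann cell markers, lay higher in the libraries labelled Islr knockout. Lists for ribosomal proteins, oxidative phosphorylation and the cell cycle lay lower. With camera at the preset correlation, 14 of 31 lists were called, 10 higher and 4 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.512), and with fry 0 were (smallest adjusted p = 0.486). Camera with an estimated correlation has little power here. Between replicate numbers 3 and 1 it did not call the interferon list (adjusted p = 0.852), where 26 of 32 members passed singly. A list that it does not call is therefore not shown to be unchanged. No member of any list passed the limma threshold over all genes, and 0 members passed when adjusted over the list alone. The count of 14 was 7 without the library labelled control 2. With the replicate block, 15 lists were called, and 3 members passed when adjusted over the list alone; 0 lists were called with the block and an estimated correlation (smallest adjusted p = 0.645) or with the block and fry (0.54).

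The collagens and other extracellular matrix genes had a median log2 fold change of 0.51 over 58 tested members, 53 of them on the higher side (camera adjusted p = 9.68e-09; adjusted p = 0.512 with an estimated correlation). Fn1, described above, had the smallest p among them. Matrix proteases and their inhibitors had a median of 0.66 over 28 members (adjusted p = 6.18e-05; adjusted p = 0.512 with an estimated correlation), with Timp3 in front. All 30 ERK-responsive transcripts were on the higher side, with a median of 0.53 (adjusted p = 2.15e-06; adjusted p = 0.512 with an estimated correlation). Their median was 0.11, 0.31 and 1.36 in replicate numbers 1, 2 and 3. Lif, a cytokine gene on this list and on that for inflammatory cytokines, stood at 441.5, 439.1 and 1670 scaled reads in the libraries labelled knockout and 392.2, 50.1 and 217.3 in those labelled control. The list for TGF-beta and BMP response had a median of 0.35 over 34 members (adjusted p = 8.85e-04; adjusted p = 0.512 with an estimated correlation); Inhba, which encodes an activin subunit, averaged 3836 ± 1831 against 1480 ± 301. Immediate-early genes, which also respond to cell dissociation, had a median of 0.40 over 26 members (adjusted p = 8.85e-04; adjusted p = 0.512 with an estimated correlation), and the phosphatase gene Dusp1 averaged 1742 ± 524 against 915 ± 345. Inflammatory cytokines and chemokines had a median of 0.90 over 28 members (adjusted p = 0.00127; adjusted p = 0.684 with an estimated correlation). In replicate number 1 the median was near 0 for 5 of these lists (0.05 for matrix, 0.03 for proteases, 0.04 for TGF-beta, 0.01 for immediate-early genes and 0.00 for cytokines), against 0.50 to 1.65 in numbers 2 and 3. Some of these calls were lost when 1 library was left out. As these fits had no block, the same-numbered partner stayed unmatched, and the loss cannot be laid to the left-out library alone. Without that labelled control 2, adjusted p was 0.0824 for proteases, 0.106 for immediate-early genes and 0.176 for cytokines; without that labelled Islr knockout 3 it was 0.773 for cytokines, and without that labelled control 3 it was 0.13 for the ERK-responsive and TGF-beta lists.

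Markers of some other cell types moved with these groups, as did signs of the libraries themselves. Unannotated loci took 0.42%, 0.39% and 0.41% of reads in the libraries labelled knockout and 0.35%, 0.26% and 0.23% in those labelled control, and 21252, 20611 and 21956 genes had reads against 20597, 19532 and 20985. The mitochondrial share was 2.66%, 1.67% and 1.93% against 1.63%, 1.69% and 2.09%. The fibro-adipogenic and fibroblast list had a median log2 fold change of 0.60 over 29 members (camera adjusted p = 6.55e-04; adjusted p = 0.684 with an estimated correlation), but its median was -0.28, 1.59 and 0.18 in replicate numbers 1, 2 and 3. Its member Hsd11b1 averaged 744 ± 286 against 384 ± 131. Endothelial markers had a median of 0.72 over 18 members (adjusted p = 0.00149; adjusted p = 0.684 with an estimated correlation), with Cldn5, a tight junction gene, at 8.0, 52.6 and 15.1 against 3.3, 7.0 and 6.8. Macrophage and immune markers had a median of 0.66 over 22 members (adjusted p = 0.00552; adjusted p = 0.684 with an estimated correlation), with Spi1 averaging 5.34 ± 4.14 against 0.939 ± 0.865. Schwann cell and glial markers had a median of 0.49 over 13 members (adjusted p = 0.00285; adjusted p = 0.512 with an estimated correlation), and the neurotrophin receptor gene Ngfr averaged 723 ± 336 against 303 ± 45.7. In replicate number 1, all 4 of these medians were below 0, from -0.28 to -0.06. Each of the 4 calls was lost without the library labelled Islr knockout 2 (adjusted p = 0.262 for fibroblast, 0.602 for endothelial, 0.109 for macrophage and 0.306 for Schwann markers). Adjusted p was also 0.179, 0.109 and 0.106 for fibroblast, macrophage and Schwann markers without that labelled control 2, 0.167 and 0.316 for endothelial and macrophage markers without control 1, and 0.104 and 0.773 for these without Islr knockout 3.

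**Figure D2:**
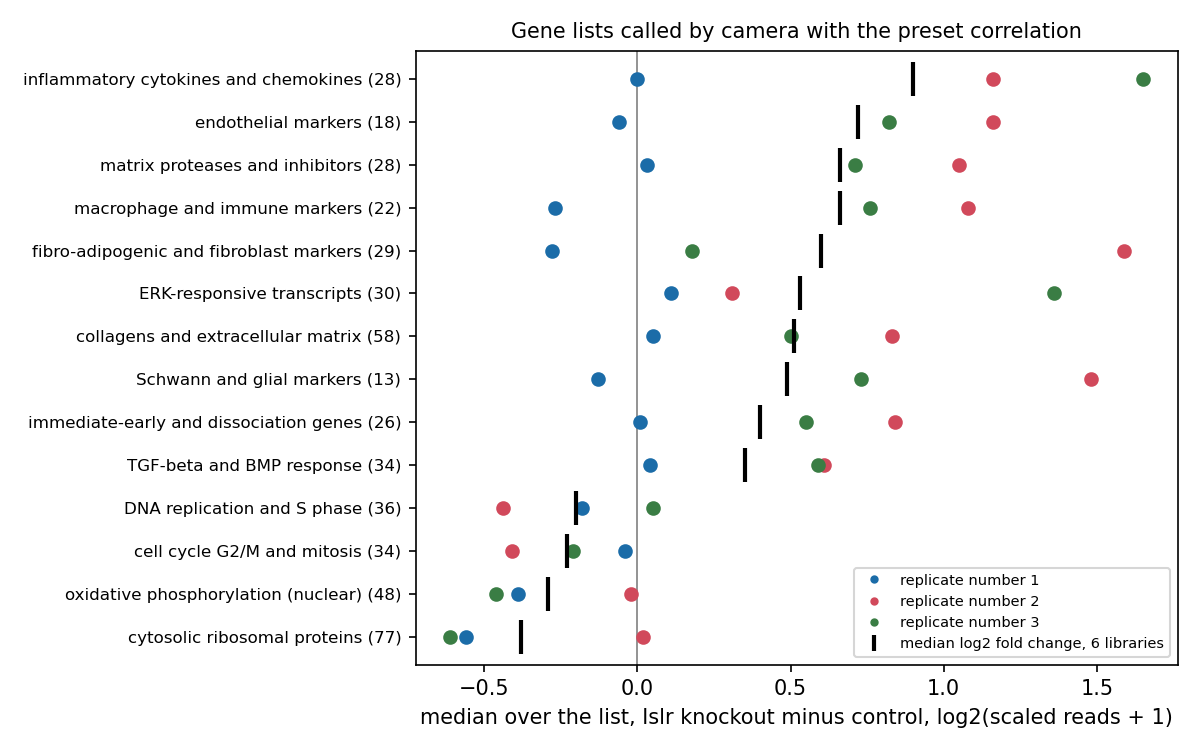
Median over each called gene list (number of tested members in brackets) of the difference between the libraries labelled Islr knockout and control, in log2(scaled reads + 1). Coloured points are the 3 replicate numbers and black ticks the median log2 fold change over 6 libraries; the fibroblast list ran from -0.28 to 1.59 and the ribosomal list from -0.61 to 0.02.

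Among the 4 lists that lay lower, the cytosolic ribosomal proteins had a median log2 fold change of -0.38 over 77 members, 75 of them on the lower side (camera adjusted p = 3.87e-17; adjusted p = 0.684 with an estimated correlation). The median was -0.56, 0.02 and -0.61 in replicate numbers 1, 2 and 3. Rpl23a, for which reads can be shared with processed pseudogenes, averaged 588 ± 344 against 1064 ± 436. Nuclear genes of oxidative phosphorylation had a median of -0.29 over 48 members (adjusted p = 4.8e-10; adjusted p = 0.512 with an estimated correlation); Ndufa4 averaged 2608 ± 536 against 3561 ± 352. Genes of G2/M and mitosis had a median of -0.23 over 34 members (adjusted p = 0.00149; adjusted p = 0.684 with an estimated correlation), and Birc5 averaged 1561 ± 830 against 2196 ± 865. Genes of DNA replication and S phase had a median of -0.20 over 36 members (adjusted p = 0.00149; adjusted p = 0.684 with an estimated correlation), and Rfc4 averaged 281 ± 73.7 against 375 ± 76.9. The G2/M and S phase calls were lost without the library labelled control 2 (adjusted p = 0.197 and 0.37, with the direction turned), Islr knockout 1 (0.0878 and 0.0518) or Islr knockout 3 (0.717 and 0.458). The medians of all 14 lists kept their sign under TMM, upper-quartile and library-size scaling.

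The other 17 tested lists were not called, with camera adjusted p from 0.0886 to 0.822. Interferon-stimulated genes were the list whose call the pairing changed: the median was 0.66 over 32 members, with adjusted p = 0.138 unblocked, 7.18e-06 with the replicate block, and adjusted p = 0.645 with the block and an estimated correlation. It was called higher without the library labelled control 3 (adjusted p = 1.03e-07), Islr knockout 1 (0.00156) or Islr knockout 2 (0.0108). Without Islr knockout 3 it was called lower (6.72e-04). These fits had no block and left the same-numbered partner unmatched, and the list was high in both libraries of number 3. Its member Tap1 had a log2 fold change of 0.89 ± 0.90 (SE). Satellite cell stem and quiescence markers had a median of 0.00 over 30 members; Fgfr4, a receptor of muscle progenitors, stood at 532.8, 396.7 and 468.7 against 557.7, 987.0 and 3159. Polarity and asymmetric division genes had a median of 0.08 over 30 members, with Egfr at 946 ± 272 against 513 ± 32.8. Myogenic differentiation genes had a median of -0.04 over 50 members, and 0.03, 1.30 and -1.85 in replicate numbers 1, 2 and 3 (adjusted p = 0.0998; adjusted p = 0.808 with an estimated correlation, which was 0.785). With camera at the preset correlation, this list was called lower without the library labelled control 2 (3.16e-12) or Islr knockout 1 (1.39e-06) and by library size alone (0.0491). It was on the higher side, not called, without control 1, control 3 or Islr knockout 2 (adjusted p = 0.295, 0.878 and 0.489), and with the replicate block it was called lower without number 1 (0.00763) or 2 (2.37e-06) and higher without number 3 (1.22e-04). ERK pathway components had a median of 0.05 over 26 members (Shc1, 3227 ± 1295 against 2214 ± 393), canonical Wnt genes 0.19 over 32 (Fzd2, 960 ± 338 against 1454 ± 490) and Notch genes 0.05 over 23 (Jag1, 839 ± 185 against 474 ± 187). The median was 0.33 for pericyte and smooth muscle markers (Acta2, 13819 ± 1701 against 22869 ± 12594), 0.41 for tenocyte and cartilage markers (Col2a1, 9.45 ± 7.84 against 28.2 ± 6.66) and 0.05 for adipocyte markers (Cd36, 50.4 ± 36.9 against 26.9 ± 13.3). The tenocyte list was called higher without the library labelled control 1 (adjusted p = 0.0411) and the Wnt list without Islr knockout 1 (0.0309).

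Metabolic and stress lists were likewise not called. The median log2 fold change was -0.06 for glycolysis and hypoxia response (Ankrd37, 26.6 ± 17.7 against 65.8 ± 35.8), -0.03 for cholesterol and fatty acid synthesis (Fdft1, 1088 ± 408 against 1681 ± 162), -0.01 for the unfolded protein and amino acid response (Asns, 2174 ± 669 against 3196 ± 918) and 0.31 for p53 targets and senescence (Mdm2, 6203 ± 748 against 3897 ± 1907). It was 0.12 for mitochondrially encoded transcripts, where mt-Nd4l, which overlaps its neighbour, stood at 10.3 scaled reads or less. It was 0.23 for replication-dependent histones, a family of near-identical copies whose member Hist1h2ab stood at 5.9 or less, and 0.04 for the imprinted growth network (H19, 69831 ± 18825 against 131784 ± 90193). The unfolded protein, Notch and imprinted lists, with medians of -0.01, 0.05 and 0.04, had means of -0.03, -0.06 and -0.22, and camera placed all 3 on the lower side. Of these lists, cholesterol synthesis was called lower without the library labelled control 3 (adjusted p = 1.3e-06) or Islr knockout 1 (6.36e-04), and the unfolded protein list lower without Islr knockout 3 (0.0225). The p53 list was called higher without Islr knockout 1 (0.0214) and with a minimum of 1 CPM in 3 libraries (0.0193), and the mitochondrial list higher without Islr knockout 2 (0.039). Another 3 lists had under 5 tested members and no set test. Islr, Sparc and Mapk3 of the list of targets in the series title are given above, Alas2 of the erythroid list stood at 6.8 or less, and Xist of the sex-linked list averaged 11796 ± 8825 against 10522 ± 4875.

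The authors' deposited table gives their own comparison of the same 6 libraries. In the authors' deposited table, 0 of 27283 genes had an adjusted p under 0.05 (smallest 0.6929), and 318 (1.17%) had an unadjusted p under 0.05, 283 higher and 35 lower in knockout. DESeq2 on the recovered reads gave an unadjusted p under 0.05 for 318 genes, and all 318 were shared with the authors' deposited table. In limma, 136 of the higher genes were shared, where independent lists would share 3.3, and 17 of the lower genes, where independent lists would share 0.1; both come from the same libraries. The authors' deposited table of GO terms rests on 262 genes, all with an unadjusted p under 0.05. It lists 146 of 1475 terms with an adjusted p under 0.05. Among them were extracellular space (69 genes, 24 expected), cell surface (42 genes, 13.3 expected) and positive regulation of the ERK cascade (19 genes, 2.89 expected).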

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

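TMM factors in limma, edgeR with TMM, the block in edgeR and DESeq2 and in lists with fry or an estimated correlation, and leaving out both libraries of a replicate number were chosen after seeing the data. The count of 0 changed genes held under each of the other scalings, filters, pseudocounts and tools without a block, and under each left-out library (0 to 0). It held in limma and edgeR with the replicate block, and moved to 7 in DESeq2 with the replicate block, all higher in the libraries labelled knockout. It moved to 93 in limma with the replicate block when both libraries of number 1 were left out, a fit on 4 libraries, and stayed 0 without number 2 or number 3. The cause was not tested. The 14 called lists became 0 with an estimated correlation, 0 with fry, and 0 for both with the replicate block (smallest adjusted p 0.645 and 0.54). Camera with the preset correlation called 7 to 17 lists when 1 library was left out, and with the replicate block 19, 6 and 17 when both libraries of number 1, 2 or 3 were left out; the cause was not tested. Estimated correlations ran from -0.017 to 0.925. The calls hold at the preset of 0.01 and not with estimated values, and no other preset was run. The size of the correlation does not by itself account for their loss. The canonical Wnt list, with an estimated correlation of -0.005, went from a camera adjusted p of 0.0886 to 0.512. With the replicate block alone, 15 lists were called, the interferon list being the 1 added. Slco2a1, Fgfr4, Lif, Inhba and Ngfr passed without number 1, and Lif with the DESeq2 block.

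Islr kept its direction under TMM, upper-quartile and library-size scaling (-2.43, -2.45 and -2.38), none past the threshold, and ran from -4.18 to -0.77 when 1 library was left out. With the replicate block it was at -3.89, -3.28 and -0.11 without number 1, 2 or 3. Of the 44 named genes, 39 kept their direction under all alternatives. The other 5 reversed in part, all with a log2 fold change not past the threshold either way. Leaving out 1 library gave -0.49 to 0.09 for Pax7, -2.52 to 0.82 for Myog, -0.22 to 0.18 for Mapk3 and -0.54 to 0.39 for Xist. With the replicate block and without number 1, Mapk3 was at 0.04 and Xist at -0.51; without number 2, Pax7 was at 0.01 and Myf5 at 0.08; without number 3, Myog was at 1.02, Mapk3 at 0.02 and Xist at -0.14. Mapk3 was at 0.00 by library size alone. The cause was not tested. With at least 16456917 reads per library, depth limits most the named genes with 10.3 scaled reads or less in every library: Pkd1l1, Spi1, mt-Nd4l, Hist1h2ab and Alas2.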

Other observations

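The comparisons between replicate numbers, the tests of Islr against Myog and of the share of genes with the block, and the count of gene lists over other splits were chosen after their results or the values behind them had been seen.

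The strongest differences in these libraries lay between replicate numbers, tested as the average over control and knockout. The 2 libraries of a number need not share them evenly. Within number 3, the knockout-minus-control median was 1.65 for cytokines, 0.76 for macrophage and 0.82 for endothelial markers. In limma with genotype as a term, 1291 of 20344 genes differed between the 3 numbers. Interferon-stimulated genes were high in both libraries of number 3: 26 of 32 rose against number 1 (median log2 difference 4.25) and 31 of 32 were lower in number 2 than in number 3 (median -4.35). Rsad2, an antiviral effector, stood at 494 and 567 scaled reads in the control and knockout libraries of number 3, and between 6.46 and 10.3 in the other 4 (log2 difference from number 1 of 5.83 ± 0.50 SE, limma adjusted p = 0.00376). Cxcl10, an interferon-induced chemokine, stood at 254 and 271 against 4.66 to 7.99. Inflammatory cytokines and chemokines rose with them for 10 of 28 members against number 1, and Cxcl5 reached 694 and 1563 where the other 4 libraries held 36.0 or less. In the same contrast 14 of 28 genes of cholesterol and fatty acid synthesis fell; Idi1 was at 103 and 133 in number 3 and at 1220 and 1468 in number 1. Camera called these 3 lists at the preset correlation (adjusted p = 6.08e-24, 3.63e-09 and 1.74e-12) and not with an estimated one (adjusted p = 0.852 for each). Markers of other cell types were also on the higher side in number 3 against number 1: macrophage (median 1.61, adjusted p = 2.32e-07; adjusted p = 0.852 with an estimated correlation), endothelial (1.25, 6.8e-06; adjusted p = 0.889) and fibroblast markers (0.61, 0.00227; adjusted p = 0.889). These genes were chosen after their values were seen.

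Replicate number 2 had lower muscle differentiation genes. Of 50 differentiation and sarcomere genes, 18 were lower than in number 1 (median log2 difference -4.78; camera adjusted p = 4.25e-23; adjusted p = 0.928 with an estimated correlation). In number 3 the list was also lower than in number 1, with 4 members past the test (median -1.50, adjusted p = 6.13e-08, or 0.889 with an estimated correlation). This drop was not shared evenly by the 2 libraries of number 3. The list was lower in that labelled Islr knockout 3 than in that labelled control 3 (median -1.85). Myog stood at 43261 in control 3 and 5737 in Islr knockout 3, against 43370 and 37228 in number 1. Myh7, a slow myosin heavy chain, was at 8.16 and 31.4 scaled reads in the control and knockout libraries of number 2 and at 2683 and 4975 in number 1 (limma adjusted p = 0.00232). Of 34 genes of G2/M and mitosis, 11 were higher in number 2 than in number 1 and 23 higher than in number 3; Ccnb1 was at 5482 and 4070 in number 2 and at 1913 or less elsewhere. Of 36 genes of DNA replication and S phase, 15 were higher in number 2 than in number 3 and 1 than in number 1. Endothelial markers were also on the higher side in number 2 against number 1 (median 1.65, 5 of 18 members past the test; adjusted p = 5.45e-08), as were macrophage markers (0.64, 1 of 22; adjusted p = 0.00602), neither with an estimated correlation (adjusted p = 0.928 for both). Each number has 2 libraries, and what the numbers mark is not given in the sources used here.

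Islr was not lower in the library labelled Islr knockout 1 (256.7 scaled reads) than in that labelled control 1 (181.1). A larger share of fibroblasts in the library labelled Islr knockout 1 than in that labelled control 1 is argued against. The median of 29 fibroblast markers was 0.28 lower in Islr knockout 1 (-0.28, quartiles -0.50 and 0.13), with Gsn at 2870 against 3661. Against this direction, 9 of the 29 were higher, among them the abundant Prrx1 (2955 against 2201). Of the 29 markers, 20 reach 10 scaled reads in every library and 5 stand on another list. A like share of fibroblasts in both libraries would give no such difference, and stays open. The only sort stated in the design is by Islr. Exchanged labels within number 1 stay open: its knockout-minus-control differences correlated over genes at 0.139 with those of number 3 and at -0.175 with those of number 2, while numbers 2 and 3 correlated at 0.089, so the value above 0.05 that was to exclude an exchange is not beyond the spread of these correlations, and genes are not independent replicates. That Islr reads follow the extent of myogenic differentiation stays open: the 3 libraries with the most Islr were also the 3 with the most Myog (3 of 3 shared), but within numbers 1 and 2 the log2 differences ran opposite ways (0.50 and -0.72 for Islr, -0.22 and 2.26 for Myog). The 2 libraries of number 1 were also the most alike, with 6.2% of genes differing by at least 2-fold, against 14.3% and 16.3% in numbers 2 and 3.

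No gene passed the limma test between the groups. Differences between replicate numbers may hide a shared effect, but with the block 4.59% of genes had an unadjusted p under 0.05, and the other 3 splits that part all 3 pairs gave 2.19% to 9.84%, so a shared effect stays open at this number of libraries. Without number 1, the blocked fit called 93 genes (89 higher and 4 lower), and 0 with the labels of 1 pair exchanged; without number 2 or 3, exchanged labels called 32 and 541 where the real ones called 0. As the real split called 0 genes, all 10 of the 10 splits reach that count by construction (highest other 51), so the count of splits decides nothing. The split that called 51 sets the libraries labelled control 1, control 3 and Islr knockout 1 against the rest, parts 1 pair only, and points to a structure of the samples by replicate number, as the 6 splits that part 1 pair gave 608 to 3261 genes at an unadjusted p under 0.05.

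The 318 genes with an unadjusted p under 0.05 in DESeq2 were mostly higher in the libraries labelled Islr knockout. The library labelled Islr knockout 3 may set most of these p-values, as it held the highest value of 206 genes. Without it, 51 (16%) kept an unadjusted p under 0.05, while 316 kept their direction. The share was 48.1% to 82.4% when another library was left out. These fits had no block. The partner labelled control 3 then stayed in unmatched, so the fall to 51 cannot be laid to Islr knockout 3 alone. The count itself was 96 without it, 907 without Islr knockout 1, 569 without control 2 and 580 without control 3. A larger share of fibroblasts in all 3 libraries labelled knockout is argued against by the fibroblast markers of number 1 (median -0.28). A share in numbers 2 and 3 stays open. The median was 1.59 in number 2, with 26 of 29 markers higher in the library labelled knockout. In number 3 it was 0.18 (quartiles -0.04 and 0.90), with 17 of 29 higher. Other splits gave as many such genes in 8 of 10 cases, the real one included (318, highest other 3077), and the other 3 splits that part all pairs gave 40 to 345. The 345 came with the labels of number 1 exchanged, a split that keeps numbers 2 and 3 as labelled. The 10 splits cannot give a share under 0.05, and an effect of the genotype stays open.

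Terms for extracellular space and for positive regulation of the ERK cascade were both enriched (Fisher's exact test, one-sided, against annotated genes with a mean of at least 1) in 6 of the 10 splits, the real one included, and in 1 of the other 3 splits that part all pairs. That 1 split exchanges the labels of number 1 and keeps numbers 2 and 3 as labelled, so it is not free of the real contrast. The real split had 19 ERK genes where 3.1 were expected, the smallest p of the 10 splits for this term (exact p = 2.81e-10); the highest other count was 47 where 29.1 were expected (exact p = 3.59e-04), among 2668 genes against 285. For extracellular space, other splits had a smaller exact p than the real one (9.53e-23, 68 genes where 17.6 were expected), among them 1 that parts all pairs (3.68e-23, 70 genes where 18.3 were expected). The splits are too few for a share under 0.05. As many lists as the 14 called by camera were reached in 2 of the 10 splits, the real one included (highest other 17), and the other 3 splits that part all pairs called 4 to 13. The 13 again came with the labels of number 1 exchanged. With the replicate block the real split called 15 and these 3 called 4, 5 and 18, the most with the labels of number 1 exchanged; the splits are again too few for a share under 0.05.

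With the replicate block, the 7 genes called by DESeq2, named after their values were seen, were Mmp9, Itga2, Naip1, Ptprf, Samd5, Lif and Scn3b, all higher in the libraries labelled knockout in each pair. Mmp9, a matrix metalloproteinase, stood at 4.56, 113 and 187 scaled reads against 1.11, 6.99 and 14.5 (log2 fold change 3.65 ± 0.66 SE, DESeq2 adjusted p = 4.94e-04), and the integrin gene Itga2 had a log2 fold change of 2.61 ± 0.48 SE (adjusted p = 5.01e-04). In limma and edgeR with the same block, 0 genes passed. In the simulated data with the block, DESeq2 made 34 false calls, against 27 in limma and 21 in edgeR. These came beside 50 planted changes per fold size, of which each tool recovered 96% to 100% from 4-fold up. The counts therefore do not give the false share among the 7, of which some may still be false. Naip1 has close paralogs with which reads can be shared.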
